A study of Homo sapiens with 6 samples.

How the data were processed

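RNA sequencing profiles of HTR8/SVneo cells, an immortalised human trophoblast line derived from early placenta, were analysed from 6 libraries. The labels placed 3 libraries in a control group and 3 in a group with HMGB1 interference, and each library was numbered 1 to 3 within its group by its title. Columns of the deposited tables were matched to samples by group name and number. Their names begin with sh in both groups, a common prefix for short hairpin RNA, while the treatment label of the control samples reads none. RNA was taken from cultured cells with TRIzol, per the labels' protocols. The labels did not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The treatment label of the interference samples speaks of lowering and of raising HMGB1 together, while the series' design text speaks of interference only. The HMGB1 level of each library was therefore read as a check of the labels.

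The authors deposited estimated counts per gene, with decimals, and TPM, abundances scaled by transcript length, for the same 64252 Ensembl gene identifiers. Between 90.8% and 91.2% of the deposited estimated counts in a library were whole within a tolerance of 1e-09, and each deposited TPM column summed to 1e+06. The genome build was hg38, per the submitters' processing notes. The aligner, the counting tool, its handling of reads that match several genes, the strand setting and the annotation were not given in the sources used here. Estimated counts may spread a read that matches several near-identical genes among them, so genes with close copies are reported as uncertain.

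Estimated counts were rounded to whole numbers. Total estimated counts per library ran from 16133400 to 17919200. A total of 16041 genes passed edgeR's filterByExpr, with its minimum count of 10 and minimum total count of 15, and these genes held between 99.86% and 99.88% of the counts. Libraries were scaled by TMM. The groups were compared with edgeR version 4.0.16 in R version 4.3.3, by the quasi-likelihood F test (glmQLFit and glmQLFTest) with the group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Log2 fold changes are interference minus control. Their standard errors were taken as the size of the log2 fold change over the square root of F. CPM values are counts per 1e+06 TMM-scaled library counts, given as mean ± SD over the 3 libraries of a group. The dispersion option of glmQLFit had not been set before the data were examined: the newer estimate of the package was run at the start, and the package's default was then taken as the main setting and the newer estimate as an alternative.

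Gene symbols came from a table of gene names, which gave a symbol for 56105 of the 64252 identifiers and for 15152 of the 16041 tested genes. Biotype and position came from GENCODE release 29 on GRCh38. Before the data were examined, 38 gene lists, the tests, the settings to be tried besides the main one and the rule for naming genes were fixed. Of 945 list entries, 943 matched a gene and 833 were tested. Lists were tested with camera, a competitive test, at a preset correlation between genes of 0.01 and adjusted over the 38 lists. Camera with an estimated correlation and fry, a self-contained rotation test, were alternatives. Genes were named by 4 rules: HMGB1, HMGB2 and HMGB3; the 10 largest rises and 10 largest falls among genes that passed the test, had a mean of at least 5 CPM, a symbol, a protein-coding biotype and groups that did not overlap; up to 4 passing members of each list by adjusted p, or the 2 members with the highest mean CPM where none passed; and the 5 smallest adjusted p-values under the conditions of the second rule. Other genes are named only with a statement that they were chosen after their values were seen. Exceptions are copies of a named gene and members that lists share, which are given as such.

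Alternatives were edgeR with RLE factors, upper-quartile factors or library size only; no low-count filter except genes at 0 in every library; a filter of 1 CPM in 3 libraries; the DESeq2 Wald test (version 1.42.0); limma (version 3.58.1) with a trend on log2(TPM + 1) and on log2(TPM + 0.1); the replicate number as a block; and leaving out each library in turn. Pairs of libraries within a group were compared by a chi-square statistic per gene over 14542 genes. It was between 3.56 and 27.4 per degree of freedom, so no pair agreed within sampling noise and all 6 libraries were counted.

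The edgeR step was tested on simulated counts for this comparison, drawn for 16041 genes from the real means, library sizes and dispersion trend. It recovered 55.7% of genes changed 1.5-fold, 87.1% of genes changed 2-fold and 96.7% of genes changed 4-fold, and 4.95% of its calls were genes that had not been changed. Simulated genes were independent and followed the trend exactly, with the same spread in both groups and no structure shared between libraries. These shares may therefore not hold for the real libraries. Read sharing between gene copies was measured as the share of 50-base windows of a gene's GENCODE release 29 transcripts that occurred unchanged in the transcripts of its copy.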

Results

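RNA sequencing compared control HTR8/SVneo cells with HTR8/SVneo cells after interference with HMGB1. HTR8/SVneo is an immortalised line of human trophoblast, the cell layer of the placenta that meets maternal tissue. The series' title concerns HMGB1, autophagy and MAPK/ERK signalling in placental trophoblast. Each group held 3 libraries. The control libraries held 17919200, 17529000 and 17776800 estimated counts, and the interference libraries held 16609500, 17290500 and 16133400.

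HMGB1 mRNA was 11.9-fold lower in the interference group. HMGB1 (ENSG00000189403), a DNA-bending chromatin protein that can also act outside the cell as a danger signal, lies on the minus strand of chromosome 13 from 30456704 to 30617597 (GRCh38). Its level was 698 ± 66.5 CPM (counts per 1e+06 TMM-scaled library counts) in control libraries and 58.4 ± 2.40 CPM in interference libraries (SD, n = 3 each). The control libraries read 771, 682 and 641 CPM and the interference libraries 58.7, 60.7 and 55.9 CPM, so each library labelled interference lay below each control library. The log2 fold change was -3.58 (SE 0.085, edgeR quasi-likelihood adjusted p = 4.73e-07). Its relatives HMGB2 (log2 fold change 0.07, SE 0.063, edgeR adjusted p = 0.642) and HMGB3 (0.18, SE 0.146, edgeR adjusted p = 0.595) did not pass the test.

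**Figure D1:**
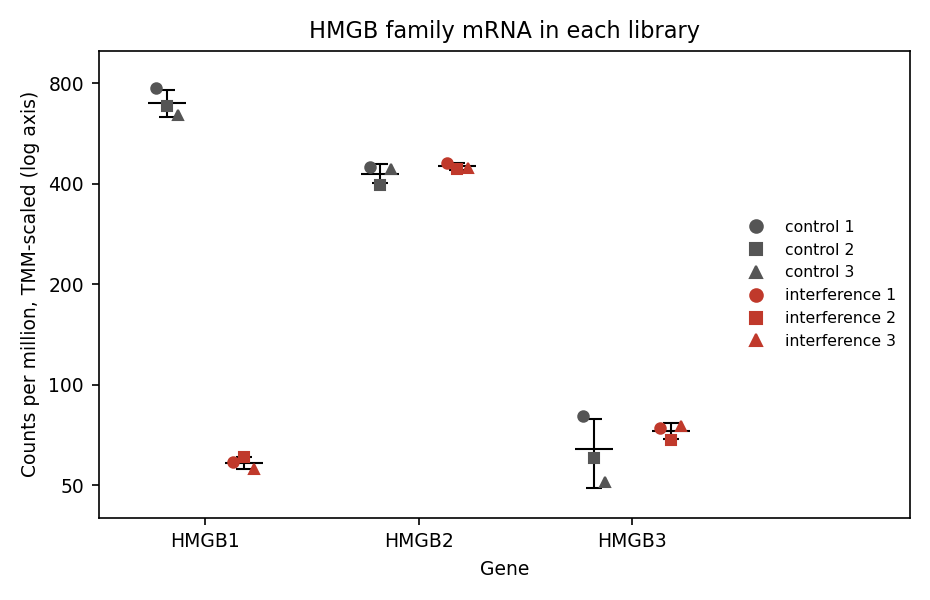
CPM, TMM-scaled, on a log axis for HMGB1, HMGB2 and HMGB3. Each point is 1 library, the horizontal mark is the group mean and the bar is 1 SD over 3 libraries. The 3 interference libraries sit between 55.9 and 60.7 CPM for HMGB1, below the 3 control libraries at 641 to 771 CPM.

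Of 16041 genes tested, 69 were higher and 31 lower after interference (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). At least 2-fold, 23 were higher and 15 lower, and 94 of the 100 were protein coding. In all 100 the groups did not overlap, as they did not in 22.0% of all tested genes, where chance gives 10%. The count depended on the libraries used. It was 218 higher and 170 lower without control 1, 508 and 374 without control 3, and 6 and 10 without control 2. Without interference 1, 2 or 3 it was 4 and 6, 3 and 6, or 13 and 6. Control libraries differed from each other by a biological coefficient of variation of 15.96%, against 7.43% among interference libraries. Of 38 gene lists fixed before the data were examined, 11 passed camera, 8 higher and 3 lower, and with an estimated correlation 1 passed, the HMGB family (adjusted p = 0.0385), where 1 of 3 members fell, HMGB1, also adjusted over the list alone. The HMGB family had a median of 0.07, a mean of -1.11 and a camera adjusted p = 4.80e-31 (lower). Since this list holds the targeted gene, its pass restates the fall of HMGB1, and no other list passed with an estimated correlation.

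Among passing protein-coding genes with a mean of at least 5 CPM, the largest rise was that of PLCXD3, from 2.03 ± 1.07 to 9.49 ± 1.01 CPM (log2 fold change 2.22, SE 0.319). RSAD2, the antiviral protein viperin, rose from 3.44 ± 1.42 to 12.8 ± 1.73 CPM (1.90, SE 0.286), and NCF2, a cytosolic subunit of the phagocyte NADPH oxidase, from 8.87 ± 1.04 to 27.0 ± 3.43 CPM (1.61, SE 0.136). DNER, a Notch-related membrane protein, rose from 12.7 ± 1.69 to 32.5 ± 2.04 CPM (1.36, SE 0.115). TFPI2, a protease inhibitor abundant in placenta, had a log2 fold change of 1.27 (SE 0.160), APCDD1L one of 1.23 (SE 0.125), the homeobox gene MKX one of 1.21 (SE 0.194), the sodium-calcium exchanger SLC8A1 one of 1.21 (SE 0.183), and G0S2, an inhibitor of adipose triglyceride lipase, one of 1.17 (SE 0.175). ANXA8 had a log2 fold change of 1.40 (SE 0.191), and 47.0% of its 50-base windows occur in its copy ANXA8L1. The share of each copy is uncertain, while the summed counts of both rose from 21.3 ± 3.46 to 47.3 ± 3.38 CPM (1.15, SE 0.122, edgeR adjusted p = 0.00819). The edgeR adjusted p-values of these 10 genes ran from 0.00264 for DNER and NCF2 to 0.0369 for MKX. PLCXD3, RSAD2, TFPI2, MKX, SLC8A1, G0S2 and ANXA8 each lost the call without each of control 2, interference 1, interference 2 and interference 3 in turn (edgeR adjusted p from 0.0560 to 0.218), and APCDD1L without interference 1 (0.0547) or interference 2 (0.0636). FOSL1, a component of the AP-1 transcription factor, was among the smallest p-values and rose from 100.3 ± 3.24 to 178 ± 5.73 CPM (0.83, SE 0.057, edgeR adjusted p = 0.00081).

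Among falls under the same conditions, EIF3CL and HMGB1 were followed by IGFBP5 and COL8A1. IGFBP5, an insulin-like growth factor binding protein, fell from 18.5 ± 9.91 to 3.35 ± 0.853 CPM (log2 fold change -2.46, SE 0.374), and COL8A1, a collagen chain, from 29.5 ± 11.1 to 7.62 ± 1.01 CPM (-1.95, SE 0.282). GFRA1, a receptor for glial cell line-derived neurotrophic factor on chromosome 10 from 116056925 to 116273467, fell from 34.2 ± 2.86 to 10.7 ± 0.469 CPM (-1.68, SE 0.0997, edgeR adjusted p = 0.000284). The transcription factor NKX2-1 (-1.31, SE 0.181), the interferon-inducible GTPase GBP1 (-1.30, SE 0.18), the heparan sulphate proteoglycan SDC2 (-1.19, SE 0.191), the kinase PRKD1 (-1.12, SE 0.132) and SUSD5 (-0.98, SE 0.157) also fell. IGFBP5, COL8A1, NKX2-1, GBP1, SDC2, PRKD1 and SUSD5 each lost the call without each of control 2, interference 1, interference 2 and interference 3 in turn (edgeR adjusted p from 0.0560 to 0.212), and EIF3CL without interference 1 (0.0547). EIF3CL had the lowest log2 fold change, at -6.06 (SE 0.584, edgeR adjusted p = 0.00652), and is uncertain. Its near-identical copy EIF3C read 334 ± 60.4 and 352 ± 8.88 CPM, 97.2% of the 50-base windows of EIF3CL occur in EIF3C, and the summed counts of both had a log2 fold change of -0.21 (SE 0.143, edgeR adjusted p = 0.525). HMGB1, GFRA1, FOSL1, DNER and NCF2 passed in each of the 6 fits that left out 1 library. GFRA1 did not pass by limma on log2(TPM + 1) (adjusted p = 0.188) or log2(TPM + 0.1) (0.219). Of the 38 named genes that passed with all libraries, 9 passed without control 2, 5 without interference 1, 6 without interference 2 and 9 without interference 3, and all 38 passed without control 1 or control 3.

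**Figure D2:**
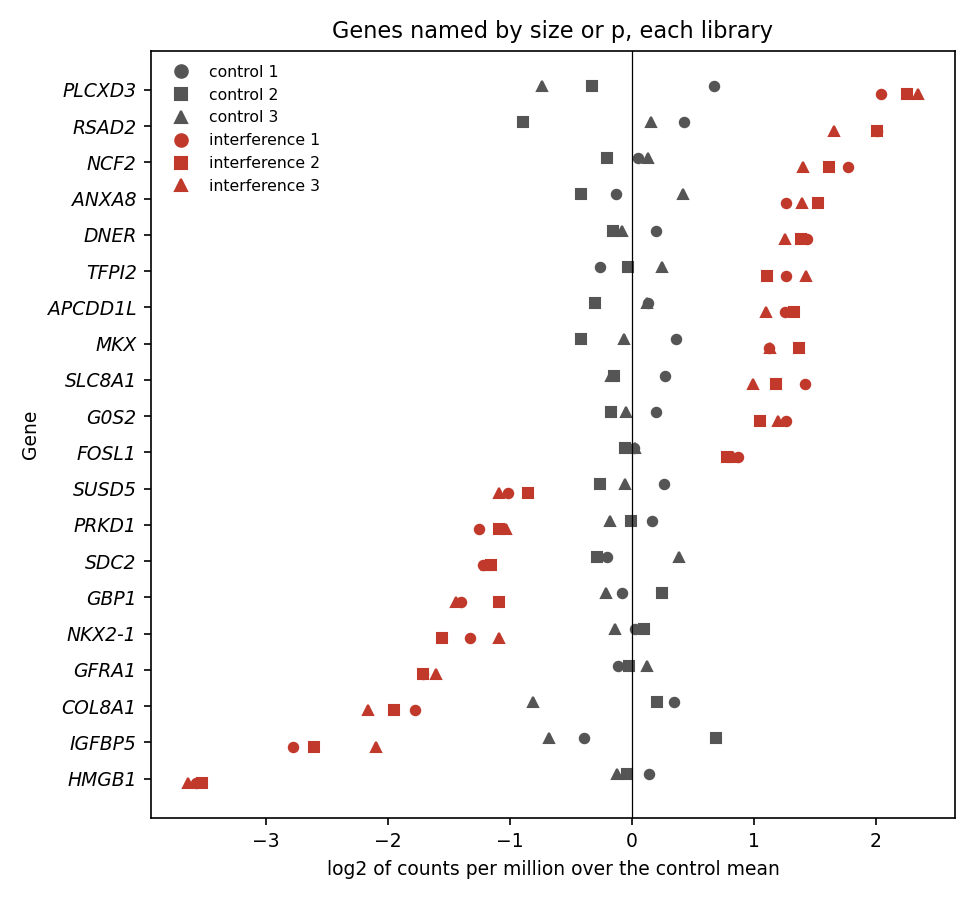
The log2 ratio of CPM in each library to the control mean, for 20 genes named by the size of their change or their p-value. EIF3CL, whose reads are uncertain, is left out, and each point is 1 library. The rule for naming these genes required groups that did not overlap, and log2 fold changes run from -3.58 for HMGB1 to 2.22 for PLCXD3.

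Genes of autophagy, which the series' title names, had 0 members past the edgeR threshold in 4 lists that together held 131 tested genes, 18 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma. Over all 16041 tested genes, 100 passed by edgeR and 2448 had an unadjusted p under 0.05. So few passed that 0 in lists of this size does not show that these genes were spared. In the core autophagy list, 0 of 41 tested members passed by edgeR and 0 adjusted over the list alone. Of these, 4 had an unadjusted p under 0.05, and DESeq2 and limma called 0. The list median was -0.03 (camera adjusted p = 0.827), and its most abundant members WIPI2 and GABARAPL1, which act in autophagosome formation, had log2 fold changes of 0.12 (SE 0.065) and 0.02 (SE 0.140). Among selective autophagy receptors 0 of 19 passed, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05 (DESeq2 0, limma 0, median 0.04, camera adjusted p = 0.655), with FKBP8 at 0.07 (SE 0.063) and SEC62 at -0.10 (SE 0.054). Among regulators of autophagy by mTORC1 and AMPK 0 of 31 passed by edgeR, 8 had an unadjusted p under 0.05, and 2 higher and 4 lower passed adjusted over the list alone. DESeq2 called 2 of them, BCL2L1 (edgeR log2 fold change 0.24, SE 0.059, past the edgeR threshold without control 3 at adjusted p = 0.0390) and, chosen after its values were seen, PRKAB2 (DESeq2 log2 fold change -0.38, SE 0.12), and limma called 0. That list's median was 0.0059 and its mean -0.12 (camera direction lower, adjusted p = 0.690), and PRKAA1, a catalytic AMPK subunit, had a log2 fold change of 0.06 (SE 0.051). PRKAA2, the other catalytic subunit, chosen after its values were seen, was among the 4 lower adjusted over the list alone (-0.65, SE 0.182, edgeR adjusted p = 0.157 over all genes). Among lysosome and TFEB target genes 0 of 40 passed, 0 adjusted over the list alone and 5 at an unadjusted p under 0.05 (DESeq2 0, limma 0). Their median was -0.0037 and their mean 0.0028 (camera direction lower, adjusted p = 0.949), with PSAP at -0.12 (SE 0.082) and GRN at -0.02 (SE 0.108). These tests concern mRNA levels only.

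The kinases and adaptors of the MAPK/ERK cascade likewise had 0 of 30 members past the edgeR threshold, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05 (DESeq2 0, limma 0). With 30 members, 0 past the edgeR threshold does not set the list apart from all tested genes. The list median was -0.04 (camera adjusted p = 0.421), and the 14-3-3 adaptors YWHAZ and YWHAB had log2 fold changes of -0.16 (SE 0.075) and -0.12 (SE 0.086). YWHAZ passed without control 3 (-0.23, edgeR adjusted p = 0.0217). Fry, which asks whether members move on balance one way, gave an adjusted p of 0.0161 with 7 of 30 members above 0. Genes that ERK signalling is known to induce stood higher: 3 of 30 tested members of the ERK output list rose, 9 adjusted over the list alone, and 29 had a positive log2 fold change (median 0.48, camera adjusted p = 2.64e-13). The list had an adjusted p = 0.508 with an estimated correlation, and 0.172 by fry. The risers were FOSL1, the transcription factor MYC (0.47, SE 0.064, edgeR adjusted p = 0.0234) and the cyclin CCND1 (0.59, SE 0.085, edgeR adjusted p = 0.0246). MYC and CCND1 lost the call without each of control 2, interference 1, interference 2 and interference 3 in turn (edgeR adjusted p from 0.0945 to 0.172). The mean of the list in control 3 was 0.62 above the control mean, within the 0.54 to 0.71 of the interference libraries, while controls 1 and 2 stood at -0.42 and -0.20.

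The immediate-early list showed the same arrangement of libraries. It shares FOS, FOSB, JUNB, EGR1 and IER2 with the ERK output list, so the lists are not separate evidence. The phosphatase DUSP1 rose (0.65, SE 0.095, edgeR adjusted p = 0.0259) as 1 of 17 tested members, and 6 passed adjusted over the list alone (median 0.46, camera adjusted p = 2.55e-07; adjusted p = 0.590 with an estimated correlation). Its list mean was 0.72 in control 3, -0.42 and -0.30 in controls 1 and 2, and 0.56 to 0.73 in interference libraries. Endoplasmic reticulum chaperone and unfolded protein response genes stood lower as a list. The chaperone CALR fell from 1330.2 ± 169 to 919 ± 13.2 CPM (-0.53, SE 0.089, edgeR adjusted p = 0.0443), as 1 of 22, and 6 were lower adjusted over the list alone (median -0.18, camera adjusted p = 5.03e-06; adjusted p = 0.590 with an estimated correlation). Control 3 again lay near the interference libraries, at -0.18 against -0.23 to -0.19, with controls 1 and 2 at 0.09. In the JNK and p38 list 1 of 23 rose, DUSP1 again, and 6 were higher and 2 lower adjusted over the list alone (median -0.01, mean 0.08, camera direction higher, adjusted p = 0.228, or 0.00778 without control 3). DUSP1 and CALR lost the call without each of control 2, interference 1, interference 2 and interference 3 in turn (edgeR adjusted p from 0.122 to 0.261).

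**Figure D3:**
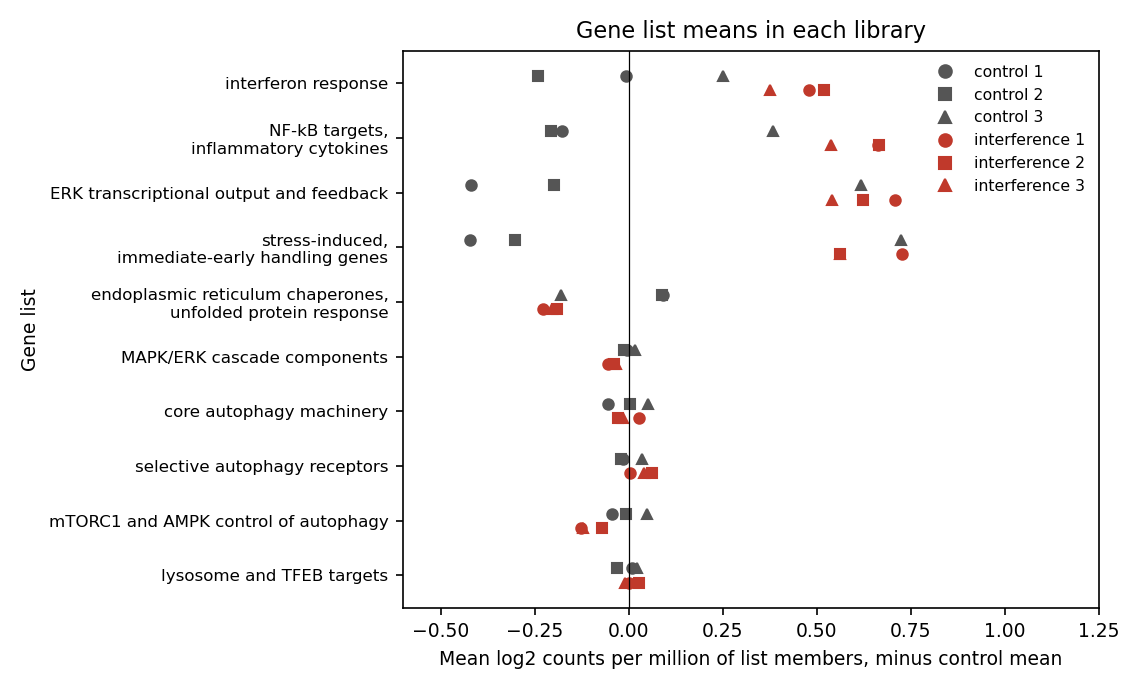
Mean log2 CPM of the tested members of 10 gene lists in each library, minus the control mean. Each point is 1 library. For the ERK output and immediate-early lists, control 3 (0.62 and 0.72) lies among the interference libraries, while for core autophagy the libraries lie between -0.054 and 0.052.

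Some interferon response genes rose. Of 32 tested members, 28 had a positive log2 fold change, 5 passed, all higher, and 12 passed adjusted over the list alone (median 0.40, camera adjusted p = 3.85e-13; adjusted p = 0.508 with an estimated correlation). RSAD2 is given above, as is the interferon-inducible GBP1, which is outside this list and fell (-1.30). OASL rose from 35.1 ± 6.92 to 72.5 ± 8.93 CPM (1.05, SE 0.148), IFIT3 from 52.9 ± 10.3 to 101.0 ± 8.58 CPM (0.93, SE 0.131), and RIGI, a cytosolic sensor of RNA, from 40.5 ± 7.65 to 73.9 ± 4.73 CPM (0.87, SE 0.129). Their edgeR adjusted p-values were 0.0235, 0.0234 and 0.0271. The remaining member to pass, DDX60, was chosen after its values were seen (0.66, SE 0.110, edgeR adjusted p = 0.0443). The list mean was 0.38 to 0.52 in interference libraries and -0.0075, -0.24 and 0.25 in controls 1, 2 and 3. NF-kB targets stood higher too, with 2 of 21 tested members up, 10 adjusted over the list alone (median 0.50, camera adjusted p = 7.21e-12; adjusted p = 0.499 with an estimated correlation). They were TNFAIP3, a feedback inhibitor of NF-kB (0.76, SE 0.112, edgeR adjusted p = 0.0259), and BIRC3 (0.92, SE 0.136, edgeR adjusted p = 0.0271). The list mean was 0.54 to 0.67 in interference libraries, 0.38 in control 3, and -0.18 and -0.21 in controls 1 and 2. RSAD2, OASL, IFIT3, RIGI, TNFAIP3 and BIRC3 each lost the call without each of control 2, interference 1, interference 2 and interference 3 in turn, with edgeR adjusted p-values up to 0.174 for BIRC3.

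FAS, the death receptor, rose from 7.45 ± 0.669 to 16.8 ± 1.85 CPM (1.17, SE 0.135, edgeR adjusted p = 0.0139) as 1 of 24 tested p53 targets, of which 2 passed adjusted over the list alone (camera adjusted p = 0.566). PMAIP1, a pro-apoptotic BCL2 family member, rose (0.65, SE 0.103, edgeR adjusted p = 0.0348) as 1 of 21 apoptosis regulators, of which 3 passed adjusted over the list alone. That list passed (median 0.09, camera adjusted p = 0.0275), with an adjusted p = 0.499 with an estimated correlation and 0.162 without control 1. It also passed by fry (adjusted p = 0.0464), and was lost by limma on log2(TPM + 1) and log2(TPM + 0.1). HMGA2, a chromatin protein, rose from 11.2 ± 0.998 to 23.9 ± 1.07 CPM (1.09, SE 0.106, edgeR adjusted p = 0.00652). It was the 1 member of 22 to pass among base excision and chromatin partners of HMGB1, also adjusted over the list alone (median 0.08, camera adjusted p = 0.0447; adjusted p = 0.628 with an estimated correlation), and the list's call was lost without each library except control 1, up to adjusted p = 0.218 without control 2. FAS lost the call without control 2 (0.0697), interference 1 (0.116) or interference 2 (0.125), and HMGA2 without interference 1 (0.0547) or interference 2 (0.0618). PMAIP1 lost it without each of control 2, interference 1, interference 2 and interference 3 in turn (edgeR adjusted p from 0.136 to 0.196).

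In the extravillous trophoblast list, drawn up for the invasive lineage, 17 of 25 entries were tested. HLA-G, CSH1 and MMP12 had 0 counts in every library, so the list does not stand for that lineage as a whole. Of the 17, 2 fell, and 2 higher and 3 lower passed adjusted over the list alone (camera adjusted p = 0.228). The integrin subunit ITGB1 fell from 1223 ± 27.9 to 872 ± 4.35 CPM (-0.49, SE 0.050, edgeR adjusted p = 0.0074) and fibronectin, FN1, from 478 ± 66.7 to 287 ± 10.8 CPM (-0.74, SE 0.097, edgeR adjusted p = 0.023). Among matrix protease and invasion genes 2 of 21 rose, TFPI2 and the hyaluronan receptor CD44 (0.61, SE 0.081, edgeR adjusted p = 0.023), and 3 passed adjusted over the list alone (camera adjusted p = 0.106, or 0.0428 without control 2). In the extracellular matrix and integrin list 1 of 28 fell, COL8A1, with 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.590). Vimentin, VIM, an intermediate filament of mesenchymal cells, rose from 1043 ± 21.4 to 1436 ± 31.3 CPM (0.46, SE 0.051, edgeR adjusted p = 0.012). It was 1 of 20 in the mesenchymal and stromal list, which had 1 higher and 4 lower adjusted over the list alone (median -0.03, camera adjusted p = 0.608). FN1, CD44, TFPI2, COL8A1 and VIM lost the call without each of control 2, interference 1, interference 2 and interference 3 in turn (edgeR adjusted p from 0.0561 to 0.172), and ITGB1 without each interference library in turn (0.0774 to 0.116).

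The trophoblast identity list had 0 members past the edgeR threshold (14 tested, 4 at an unadjusted p under 0.05, 3 by DESeq2, 0 by limma, 4 higher adjusted over the list alone), a median of 0.12 and camera adjusted p = 0.0392. Its list mean was 0.10 in control 1, -0.10 in control 2 and -0.0057 in control 3, against 0.078 to 0.085 in interference libraries, so the groups overlapped. The camera call was lost with an estimated correlation (adjusted p = 0.628) and without each library except control 1, up to adjusted p = 0.269 without control 2. KRT8 and PARP1, its most abundant members, had log2 fold changes of -0.06 (SE 0.118) and -0.05 (SE 0.066). The syncytiotrophoblast list had 0 of 11 past the edgeR threshold, 3 at an unadjusted p under 0.05 and 0 by DESeq2 or limma (camera adjusted p = 0.579), with SDC1 at 0.30 (SE 0.124) and PSG4 at 0.54 (SE 0.258). Without control 1 SDC1 and PSG4 passed (edgeR adjusted p = 0.0467 and 0.0281). Endothelial markers had 0 of 8 past the edgeR threshold, 1 at an unadjusted p under 0.05 and 0 by DESeq2 or limma, with ENG at 0.13 (SE 0.070) and EGFL7 at -0.02 (SE 0.094). Immune and blood cell markers had 0 of 5 past the edgeR threshold, 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma, with CD68 at 0.08 (SE 0.126) and HBA1 at -0.20 (SE 0.359). The syncytiotrophoblast, endothelial and immune lists had 0 members past the threshold adjusted over the list alone. The endothelial list had a median of -0.06, a mean of 0.0037 and a camera adjusted p of 0.873 (higher), and the immune list a camera adjusted p of 0.953.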

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

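HMGB1 fell and passed the threshold under all alternatives tried, with log2 fold changes from -3.63 to -3.32. Every alternative kept the direction of the 100 genes, except that 1 gene was not tested with the filter of 1 CPM in 3 libraries. That was nearly fixed in advance, since the groups did not overlap in any of the 100 and each alternative used the same libraries. NCF2, DNER and FOSL1 also passed in all 16 alternatives. The newer dispersion estimate gave 86 higher and 32 lower, and 99 of its calls were among the 100. It was run at the start, and the default was taken as the main setting after the data were seen. Scaling by RLE factors, upper-quartile factors or library size only gave 72, 71 and 68 higher and 31, 30 and 24 lower.

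Counts of genes moved more under other settings, and the cause was not tested. With no low-count filter, 27636 genes were tested and 198 were higher and 92 lower, 48 and 30 of them at least 2-fold. DESeq2 called 288 higher and 210 lower, 57.8% higher against 69% in edgeR, with 40 and 28 at least 2-fold, and gave no adjusted p for 2179 genes. Limma called 13 higher and 8 lower on log2(TPM + 1), 8 and 6 at least 2-fold, and 12 higher and 7 lower on log2(TPM + 0.1), 7 and 5 at least 2-fold. Same-numbered libraries did not deviate together (correlations of -0.091, 0.0067 and -0.055). With 3 libraries per group such correlations cannot exclude a pairing, and the labels gave only a number. A fit with the replicate number as a block called 3 higher and 7 lower, 2 and 7 at least 2-fold. Of the 38 named genes that passed, limma lost 27 and 28 under these pseudocounts and the block 31.

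Leaving out 1 library gave 3 to 508 genes higher and 6 to 374 lower, or 2 to 107 and 6 to 36 at least 2-fold. The lowest counts came without interference libraries and the highest without control 3. Fits without 1 library have fewer samples, which lowers power, yet control 1 and control 3 raised the counts when left out. Between 7 and 13 gene lists passed in these fits. Limma passed 7 lists under either pseudocount, camera with an estimated correlation 1 and fry 3. The HMGB family list was lost on log2(TPM + 1) (adjusted p = 0.0856) and log2(TPM + 0.1) (0.0784), while core histones passed on both (adjusted p = 0.0192 on the latter, range 0.0192 to 0.779). The matrix protease list passed with no low-count filter (adjusted p = 0.0435, range 0.0435 to 0.508). The ERK output list had an adjusted p of 0.508 with an estimated correlation and 0.172 by fry, and the MAPK/ERK cascade list one of 0.0161 by fry. The cholesterol synthesis list, which did not pass, turned to lower without control 1 (adjusted p = 0.00107, range 0.00107 to 0.977 over the libraries left out) and was higher without control 3 (0.0268). The G2 and mitosis list ran up to 0.889 and the fatty acid synthesis list up to 0.368, both without control 1, and the base excision list up to 0.218 without control 2. Genes changed 1.5-fold were recovered in 55.7% of cases on simulated counts, so smaller changes may often be below detection. The simulation lacked the unequal spread of the groups and any structure shared between libraries, so the real share may differ.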

Other observations

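Of the tests weighed here, those on correlations between libraries, on depth, on the interferon list and on the pseudogene ratio were chosen after related values had been seen. Besides the lists above, ABCC2, a multidrug transporter, rose from 2.23 ± 0.177 to 4.89 ± 0.121 CPM (log2 fold change 1.13, SE 0.189, edgeR adjusted p = 0.0448; SD, n = 3), as 1 of 21 tested NRF2 targets, also adjusted over the list alone (camera adjusted p = 0.659). ABCC2 lost the call without each of control 2, interference 1, interference 2 and interference 3 in turn (edgeR adjusted p from 0.173 to 0.229). S phase genes had a median of 0.0092 and a mean of 0.00010 (26 tested, camera direction lower, adjusted p = 0.932), with MCM4 at 0.0039 (SE 0.059) and RRM2 at 0.05 (SE 0.094). G2 and mitosis genes stood lower as a list (28 tested, 0 past the edgeR threshold, 6 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma, median -0.07, camera adjusted p = 0.0275; adjusted p = 0.779 with an estimated correlation), with TOP2A at -0.02 (SE 0.060) and TPX2 at -0.07 (SE 0.062). That call was lost without control 1 (0.889), interference 1 (0.115) or interference 2 (0.0709). The list mean was 0.14, -0.0076 and -0.13 in controls 1, 2 and 3 and -0.10 to -0.03 in interference libraries, so the groups overlapped, with control 3 the lowest library. Fatty acid synthesis genes stood higher as a list (15 tested, 0 past the edgeR threshold, 3 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma, 1 higher adjusted over the list alone, median 0.16, camera adjusted p = 0.0275; adjusted p = 0.750 with an estimated correlation), with SCD at 0.50 (SE 0.279) and ACLY at -0.07 (SE 0.061). That call was lost without control 1 (0.368) or interference 1 (0.0540). The list mean was 0.24 in control 3, -0.22 and -0.02 in controls 1 and 2, and 0.17 to 0.20 in interference libraries.

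The remaining lists did not pass camera. Adjusted p was 0.753 for HMGB1 receptors and adaptors (direction higher, median 0.09, mean -0.15; DIAPH1 -0.06, IRAK1 -0.0066), 0.228 for the integrated stress response (MTHFD2 -0.24, AARS1 -0.02), 0.566 for heat shock proteins (HSP90AA1 0.20, HSP90AB1 -0.12), 0.228 for hypoxia targets (ERO1A -0.03, SLC2A3 0.19) and 0.873 for glycolysis (GAPDH -0.02, PKM -0.05). It was 0.932 for cholesterol synthesis (direction higher, median -0.02, mean -0.0034; LDLR 0.46, DHCR24 0.09), 0.228 for the TGF-beta response (SMAD3 0.27, TGFBR1 -0.08), 0.337 for core histones (H3-3B 0.14, H1-0 0.07), 0.337 for cytosolic ribosomal proteins (RPL4 -0.18, RPS2 -0.06), 0.931 for mitochondrially encoded mRNAs (MT-CO1 0.12, MT-ND4 -0.24) and 0.953 for nuclear-encoded oxidative phosphorylation (ATP5F1B -0.09, SDHA 0.05). Values after gene names are log2 fold changes. Adjusted over the list alone, the integrated stress response had 4 members higher and 2 lower, TGF-beta 3 higher and 1 lower, glycolysis 2 higher, heat shock 1 higher, and S phase, G2, receptors, hypoxia, cholesterol, histones, ribosomal, mitochondrial and oxidative phosphorylation 0. Together with the fatty acid, S phase, G2, trophoblast identity, syncytiotrophoblast, endothelial and immune lists, these made 18 lists with 350 tested genes. They were pooled because 0 of their members passed by edgeR, so that 0 is not a result. Of the 350, 66 had an unadjusted p under 0.05, as did 2448 of all 16041 tested genes. DESeq2 called 16 of the 350 and limma 0. Without control 3 the TGF-beta (0.0118) and hypoxia (0.0268) lists passed, and SCD, LDLR, DHCR24, SMAD3, HSP90AB1, MTHFD2, RPL4, MT-ND4 and ATP5F1B passed with edgeR adjusted p from 0.00842 to 0.0412. Cholesterol synthesis passed without control 3 (0.0268) or, lower, without control 1 (0.00107), and the integrated stress response without control 1 (0.00893). Lineage genes chosen after their values were seen did not all go one way over the 6 libraries, before TMM scaling. KRT7 read 0.81 to 2.12 CPM and CDH1 0.06 to 0.619 CPM, against 1032 to 1477 CPM for VIM. Other trophoblast list members were well expressed: KRT8 read 541 to 721, KRT18 309 to 407, GATA2 83.0 to 99.9 and TFAP2A 70.3 to 103 CPM. Of the stromal list, PDGFRA read 0.11 to 0.99 CPM and DCN 0. Other stromal list members were abundant: COL5A2 read 948 to 1126, SPARC 815 to 1062 and COL1A1 217 to 376 CPM. ELF5 and CDX2, of the trophoblast list, read 0 in every library.

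Copies of genes moved with or against their partners. HMGB1P5 and HMGB1P6, processed pseudogenes chosen after their values were seen, fell with HMGB1 (log2 fold changes -3.83 and -3.98, SE 0.169 each), and 60.1% and 52.9% of their 50-base windows occur in HMGB1, as 0% of those of HMGB2 do. HMGB1 reads counted at the pseudogenes could account for this, and an action of the interference on pseudogene transcripts stays open, since their log2 fold change differed from that of HMGB1 by -0.25 (SE 0.189) and -0.40 (SE 0.189), pseudogene minus HMGB1. For EIF3CL the summed counts with EIF3C had a log2 fold change of -0.21 (SE 0.143), within 1 SE of the bound of -0.3 that would have argued against shared reads, so reads passing between the copies may account for its fall. ZBTB45P1 read 0.969 to 1.51 CPM in controls and 0 after interference while ZBTB45P2 read 0 and 1.48 to 1.90 CPM, also chosen after their values were seen, with 99.9% of windows shared.

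The ERK output, immediate-early and endoplasmic reticulum chaperone lists may follow a state that also varies between control libraries. Within each list, so that list means play no part, the difference of control 3 from control 1 correlated across members with interference minus control 2 at r = 0.83, 0.83 and 0.45 in the order given, and that of control 3 from control 2 with interference minus control 1 at r = 0.92, 0.92 and 0.78, with no library in common, while control 1 minus control 2 against interference minus control 3 gave 0.41, 0.46 and 0.52. These lists were weighed because control 3 had been seen to lie with the interference libraries on them. Genes are not independent replicates, and the ERK output and immediate-early lists share members, so their matching r values rest partly on the same genes. The r of the last pairing adds no separate evidence, since its covariance follows from those of the other pairings. In the same order of pairings r was 0.03, 0.21 and 0.18 over all 16041 tested genes and 0.16, -0.053 and -0.21 in core autophagy. For NF-kB targets it was 0.26, 0.33 and 0.098, so whether they follow such a state stays open. Spearman rank correlations set the lists less apart. In that order they were 0.66, 0.88 and 0.52 for ERK output and 0.61, 0.84 and 0.50 for immediate-early genes. Chaperone genes had 0.21, 0.65 and 0.55, all tested genes 0.0078, 0.31 and 0.30, and core autophagy 0.17, 0.11 and 0.11. Depth cannot be told apart from the groups, since the interference totals (16133400 to 17290500) all lie below the control totals (17529000 to 17919200), although control 3, at 17.8 in units of 1e+06, lies between the other controls. FOSL1 read 102 CPM in control 3 and 102 and 96.5 CPM in controls 1 and 2, and an effect of HMGB1 on these lists stays open, untested apart from such a state.

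Of the interferon response genes RSAD2, OASL, IFIT3, RIGI and DDX60 rose, 28 of 32 members had a positive log2 fold change, and among those that did not pass, chosen after their values were seen, IFIT2 (0.97, edgeR adjusted p = 0.0518), ISG15 (0.70), STAT1 (0.02), MX1 (0.15) and OAS1 (-0.0068) spanned a wide range. Correlations of the same kind were -0.15 and 0.56 across the 32 members, 1 under 0.1 and 1 over 0.3. A state that also varies between controls therefore stays open. In the remaining pairing, control 1 minus control 2 against interference minus control 3, r was 0.67. That value adds no separate evidence, since its covariance follows from those of the other pairings. A response to double-stranded RNA from a hairpin could give a rise like the list median of 0.40. It cannot be told apart from an effect of lower HMGB1, since the interference libraries share 1 treatment and no other construct against HMGB1 is in the series. Column names begin with sh in both groups, so controls may carry a hairpin too, though their treatment label reads none.

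The 6 libraries can be split 10 ways into 3 and 3, which is too few for a share under 0.05. In the real split 100 genes passed, and the highest of the other splits had 1, so 1 of the 10 splits reached the real count. For gene lists, 4 of the 10 splits had as many as the real split, 11 against at most 13. The 3 splits with more, at 12, 13 and 13, each set controls 1 and 2 with an interference library against control 3 with the others, which points to a structure of the samples other than the groups.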
